A study of Mus musculus with 8 samples.

How the data were processed

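RNA from 8 mouse cell samples was measured on Affymetrix oligonucleotide arrays, 1 array per sample. Per the labels, 3 arrays held tumour cells, each from a different mouse, 2 held bone marrow B lineage cells of IRF4 knockout mice and 3 held bone marrow B lineage cells of wild type C57BL/6 mice. IRF4 is a transcription factor of lymphoid cells that acts in pre-B cell development. Per the labels, the IRF4 knockout cells were sorted as positive for CD19 and negative for surface IgM, and the wild type cells were in addition sorted as positive for CD25, which 1 of the label fields leaves out. The labels give no genotype and no gate for the tumour cells, and do not say whether the control arrays came from separate mice. Total RNA was extracted with RNeasy columns and labelled with the Affymetrix One-Cycle kit, per the labels' protocols. The protocol text also speaks of newly transcribed RNA, but each sample is labelled as total RNA.

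The deposited table holds 1 value per probe set and array on a log2 scale. Per the submitters' processing notes, GCRMA and limma were used by the authors, and their versions, roles and order are not given in the sources used here. GCRMA corrects each probe for background with the help of its base content, normalizes arrays by quantiles and summarises the probes of a probe set. It gives values near the background little spread, so differences among low values are compressed. The deposited values ran from 1.79 to 13.8, with no missing value, and the array medians lay between 5.1 and 5.2, so the arrays were not normalized again. Scanner files were not used here. The number of arrays limits the precision of each value.

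Of the 45101 probe sets, 64 are Affymetrix controls and were used only to check quality. A platform annotation gave 34945 probe sets exactly 1 gene symbol, 932 several and 9160 none, and 34741 probe sets were matched to a mouse gene table of assembly GRCm38.p6 through their gene identifiers. That table was used only for names and for which genes neighbour each other, and since no genome build is given for the deposited values no coordinates are printed. Among the probe sets with 1 symbol, the one with the highest mean over the 8 arrays stood for its gene, which left 18193 genes, 9010 of them with several probe sets. Cd19 was to be reported but is not named by the annotation used here.

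Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) on the deposited log2 values. A single model held all 8 arrays in 3 groups, because a group of 2 arrays gives little information on its own spread. The 3 comparisons were tumour against wild type, tumour against IRF4 knockout, and IRF4 knockout against wild type, and genes were counted that changed the same way in the tumours against both control groups. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes, with no minimum fold change and no filter on low values. Fold changes are differences of mean log2 values, and their standard errors (SE) come from the model. Every adjusted p for a gene is limma's. Gene lists for stages, pathways and other cell types were written down from textbook knowledge, 34 in all, and 33 with at least 5 measured members were tested against all other genes with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 33 lists within a comparison. The same test with an estimated correlation was an alternative, as was fry, which asks whether a list's genes move on balance in 1 direction. Members of a list were also counted after adjustment over the list alone. Some lists share genes, so called lists are not all separate results. Another list also held 14 of 18 late pre-B, 17 of 30 leukaemia and lymphoma and 11 of 28 B lineage transcription factor genes. The same held for 6 of 14 progenitor and 6 of 19 early B stage genes.

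The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Irf4, Il2ra and Ighm. It adds, for each comparison and direction, the 8 genes with the largest change among called genes whose groups did not overlap and whose higher group mean lay above 6.07, the median of all gene means. It also takes up to 4 members of each described list with the largest change. Symbols of uncharacterised genes were left out, and immunoglobulin and T cell receptor segments were described only as groups. The immunoglobulin group was taken by symbol (Igh, Igk, Iglv, Iglc and Iglj), so it also holds constant region genes such as Igha and Ighm. The alternatives were a filter on dim genes, a floor of 4 on the log2 values, all probe sets, the mean of all probe sets of a gene, centring on array medians, a repeated quantile normalization, a trended and robust prior, array weights, only the groups compared, a minimum fold of 2, the replicate number as a block, and leaving out each array in turn. The test was tried on simulated data for all 18193 genes. For tumour against wild type it recovered 87% of genes set to change 2-fold and 96% of those set to change 4-fold, with 5 unchanged genes called. These shares were 78% and 95%, with 11 unchanged genes called, for tumour against IRF4 knockout, and 70% and 98%, with 7 called, for IRF4 knockout against wild type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.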

Results

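Gene expression was measured on 8 arrays, 3 of spontaneous mouse pre-B cell lymphomas, 2 of bone marrow B lineage cells from IRF4 knockout mice and 3 of bone marrow pre-B cells from wild type mice. The series was made to find genes that differ between tumour cells and control cells. Levels are given as means of deposited log2 values ± SD over the arrays of a group (n = 3, 2 and 3 for tumour, IRF4 knockout and wild type). Where the lower mean of a comparison lies under the array medians (5.1 to 5.2), the fold depends on how GCRMA treats weak signal and is not exact. The median SD of a gene within a group was 0.142, 0.144 and 0.132 on that scale. Nothing states that the control arrays came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

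Irf4 transcript was detected in all 3 groups, at 12.05 ± 0.12 in tumours, 11.83 ± 0.12 in IRF4 knockout and 12.48 ± 0.12 in wild type cells. It was lower in IRF4 knockout than in wild type cells by a log2 difference of -0.64 (SE 0.12, adjusted p = 0.0217). That call ended without IRF4 knockout array 2 (-0.56, adjusted p = 0.152) and without wild type array 1, 2 or 3 (adjusted p = 0.0626, 0.0676 and 0.051). Over all alternatives the adjusted p ran from 0.00838 to 0.152. Irf4 was also lower in tumours than in wild type cells (-0.42, SE 0.11, adjusted p = 0.0202), a call that ended without tumour 1 (0.0668) or wild type array 2 (0.0755), within a range of 0.00931 to 0.865. With the mean of all probe sets its sign turned (0.04, adjusted p = 0.865), so the direction for Irf4 in tumours rests on the probe set used. The labels do not say which part of the gene was deleted or whether the probe set lies in it, so the level checks no label. Il2ra, which encodes CD25, followed the sort gates, with 9.88 ± 0.23 in the wild type cells sorted on CD25 and 5.56 ± 0.32 in IRF4 knockout cells, and is not a finding between the control groups. It was 4.83 ± 0.54 in tumours. Ighm, the constant region of the IgM heavy chain, was 12.37 ± 0.25 in tumours, 12.99 ± 0.17 in IRF4 knockout and 13.52 ± 0.03 in wild type cells. Its fall in tumours passed against wild type cells (-1.15, SE 0.14, adjusted p = 0.000487) and against IRF4 knockout cells (-0.62, SE 0.16, adjusted p = 0.0255), where it was lost in 6 of 17 alternatives. Among these were leaving out IRF4 knockout array 1 (0.126) or 2 (0.0541) and the mean of all probe sets, which turned the sign (0.04, adjusted p = 0.869), within 0.00824 to 0.869. Between the 3' and 5' control probe sets of Gapdh, a measure of RNA integrity and labelling, the log2 difference was 1.56 to 1.67 on tumour arrays, 2.23 to 2.37 on IRF4 knockout arrays and 2.59 to 3.02 on wild type arrays, so it moved with the groups. For beta-actin it was 0.72 to 1.07 over all arrays.

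Compared with wild type pre-B cells, the tumours expressed far more of several genes, some of which had weak signal in the wild type cells. Crhbp, which encodes a binding protein of corticotropin-releasing hormone, reached 11.29 ± 0.49 in tumours against 4.40 ± 0.22 in wild type cells, a value under the array medians (log2 difference 6.89, SE 0.30, adjusted p = 5.38e-06). Umod, the gene of the kidney protein uromodulin, was 64.3-fold higher (6.01, SE 0.28) and Prss23, a serine protease gene, 49.1-fold higher (5.62, SE 0.13). Popdc3, Car3, Gpm6b, Ltbp2 and Ydjc followed at 26.6- to 37.5-fold, with weak signal in wild type cells for Popdc3 (3.66 ± 0.16) and Ltbp2 (3.18 ± 0.35). In the other direction, Jchain, the joining chain of polymeric immunoglobulin, was 75.1-fold lower in tumours (4.05 ± 0.33 against 10.28 ± 0.75, log2 difference -6.23, SE 0.35, adjusted p = 1.62e-05). Jchain was as low on the IRF4 knockout arrays (4.02 and 3.87), so it set the wild type arrays apart and not the tumours. Bex1, Steap4, Ly6d, Gpr171, Ccr9 and Vasn were 38.6- to 65.9-fold lower in tumours. Xist, the RNA that silences an X chromosome in female cells, was 97.4-fold lower (6.02 ± 0.29 against 12.63 ± 0.16), and Y-linked transcripts were present on the arrays of tumours 1 and 3.

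Genes of ribosome production rose together in the tumours. Of 30 measured members of the ribosome biogenesis and Myc target list, 28 were higher than in wild type cells and 0 lower (29 and 0 adjusted over the list alone), with a median log2 difference of 1.37 (camera adjusted p = 2.88e-15, and adjusted p = 0.053 with an estimated correlation). Srm, which makes spermidine, rose 11.3-fold, Wdr12, a ribosome assembly factor, 5.60-fold, and Fbl, the nucleolar RNA methyltransferase fibrillarin, 5.17-fold. Myc itself rose 3.61-fold (9.46 ± 0.05 against 7.61 ± 0.36). Of the oxidative phosphorylation genes 19 of 24 rose and 0 fell (20 and 0 adjusted over the list alone, median 0.57, camera adjusted p = 6.78e-08, and adjusted p = 0.203 with an estimated correlation). Atp5b rose 2.42-fold. Of 29 DNA replication genes 17 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.78, camera adjusted p = 2.6e-06, and adjusted p = 0.288 with an estimated correlation). Tk1 (thymidine kinase) rose 4.97-fold and Rfc4 (a clamp loader subunit) 4.21-fold. Glycolysis genes rose at 11 of 16 and fell at 2 (12 and 2 adjusted over the list alone, median 0.89, camera adjusted p = 0.000411, and adjusted p = 0.131 with an estimated correlation). Ldha rose 6.75-fold. Cholesterol synthesis genes rose at 12 of 17 and fell at 2 (13 and 2 adjusted over the list alone, median 1.04, camera adjusted p = 6.8e-05, and adjusted p = 0.206 with an estimated correlation). Msmo1 rose 4.82-fold and Sqle 3.89-fold, while Insig1, which restrains sterol synthesis, fell 3.79-fold. The mitosis list was called higher at 11 of 29 members, with 1 lower (13 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.019, and adjusted p = 0.602 with an estimated correlation). The call was lost in 7 of 18 alternatives, among them fry (adjusted p = 0.102) and leaving out tumour 3 (0.0895) or wild type array 1 (0.1), within a range of 0.00449 to 0.602. The Gapdh 3' to 5' difference was lower on the tumour arrays (1.56 to 1.67) than on the wild type arrays (2.59 to 3.02). That of beta-actin overlapped between these groups. Markers of several other cell types were lower too.

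Targets of NF-kB and immediate early genes were far lower in the tumours than in wild type cells. Of 17 NF-kB targets 16 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -2.55 (camera adjusted p = 1.19e-13, and adjusted p = 0.0254 with an estimated correlation). Nfkbie fell 24-fold, the chemokine gene Ccl3 21-fold and Tnfaip3 15.5-fold (8.44 ± 0.36 against 12.40 ± 0.07, SE 0.17, adjusted p = 5.38e-06). Nfkbie and Tnfaip3 encode inhibitors of NF-kB signalling that NF-kB itself induces. Of 20 immediate early and dissociation stress genes 16 fell and 0 rose (17 and 0 adjusted over the list alone, median -2.39, camera adjusted p = 1.63e-12, and adjusted p = 0.0889 with an estimated correlation). Ier3 fell 31-fold, Atf3 17.8-fold and Junb 13.4-fold. Interferon-stimulated genes fell at 16 of 22 and rose at 1 (16 and 1 adjusted over the list alone, median -1.23, camera adjusted p = 1.45e-08, and adjusted p = 0.0889 with an estimated correlation). Mx1 fell 5.63-fold and Irf7 4.16-fold. Targets of p53 fell at 10 of 20 and rose at 4 (10 and 6 adjusted over the list alone, median -0.50, camera adjusted p = 0.0037, and adjusted p = 0.0922 with an estimated correlation). Plk2 fell 30.1-fold. Neutrophil markers fell with these lists at 11 of 16 members. On the same tumour arrays the Gapdh difference was lower (1.56 to 1.67 against 2.59 to 3.02), while that of beta-actin overlapped.

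Genes of the B lineage moved in different directions. The tumours expressed more of the surrogate light chain gene Igll1 than wild type cells (12.85 ± 0.18 against 9.56 ± 0.16, 9.81-fold, SE 0.13, adjusted p = 4.21e-06) and more Enpep, a surface peptidase of early B cells (7.66-fold), but 13-fold less Dntt, the DNA polymerase that adds nucleotides at V(D)J joints. This early B stage list had 5 of 19 members higher and 8 lower (6 and 9 adjusted over the list alone) and was not called (camera adjusted p = 0.54, median -0.50). Of 28 B lineage transcription factors 19 fell and 1 rose (20 and 1 adjusted over the list alone, median -0.82, camera adjusted p = 1.61e-07, and adjusted p = 0.0254 with an estimated correlation). Id2, an inhibitor of E proteins, fell 13.3-fold and Foxo1 5.30-fold, while Ikzf3 (8.74 ± 3.30 against 11.11 ± 0.02, adjusted p = 0.252) did not pass. Late pre-B genes fell at 13 of 18 and rose at 2 (13 and 2 adjusted over the list alone, median -1.30, camera adjusted p = 1.93e-05, and adjusted p = 0.0587 with an estimated correlation). The gate gene Il2ra was among them, and Cd2 fell 10.1-fold and Spib 4.59-fold. Mature B cell genes fell at 9 of 17 and rose at 2 (11 and 3 adjusted over the list alone, median -1.15, camera adjusted p = 0.00279, and adjusted p = 0.0889 with an estimated correlation). Fcmr, a receptor for IgM, fell 26-fold. B cell receptor signalling genes fell at 14 of 27 and rose at 1 (14 and 2 adjusted over the list alone, median -0.43, camera adjusted p = 0.000258, and adjusted p = 0.117 with an estimated correlation). The kinase gene Syk fell 4.33-fold. Of 21 measured immunoglobulin segment genes 10 fell and 0 rose. The tumour arrays also had lower neutrophil and T cell markers and a lower Gapdh difference (1.56 to 1.67 against 2.59 to 3.02). The beta-actin difference overlapped between the groups.

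Markers of several other blood cell types were lower on the tumour arrays. Neutrophil markers fell at 11 of 16 (12 adjusted over the list alone, median -1.96, camera adjusted p = 2.38e-06, and adjusted p = 0.14 with an estimated correlation). Mpo fell 17.2-fold. T cell markers fell at 10 of 16 (11 adjusted over the list alone, median -0.72, camera adjusted p = 2.41e-06, and adjusted p = 0.0889 with an estimated correlation). Thy1 fell 10.6-fold. NK cell markers fell at 9 of 12 (9 adjusted over the list alone, median -0.89, camera adjusted p = 6.55e-05, and adjusted p = 0.199 with an estimated correlation). Dendritic cell markers fell at 5 of 12 (6 adjusted over the list alone, median -0.53, camera adjusted p = 0.000132, and adjusted p = 0.0889 with an estimated correlation). No member of these 4 lists rose. Also called lower than in wild type cells were adhesion (12 of 21 lower), the leukaemia and lymphoma genes (15 of 30), cytokine receptors and JAK-STAT (10 of 21), progenitor markers (8 of 14), erythroid markers (5 of 14), plasma cell markers (5 of 12) and apoptosis regulators (6 of 19). In the same order 1, 2, 4, 0, 2, 2 and 2 members rose, and adjusted over the list alone the counts of lower members were 13, 16, 11, 8, 7, 6 and 8. With an estimated correlation their adjusted p was 0.0889, 0.131, 0.14, 0.226, 0.416, 0.264 and 0.264. The call on apoptosis regulators ended without tumour 1 (adjusted p = 0.0603, range 0.00997 to 0.264, with 4 of 18 alternatives not passing). Not called were macrophage and monocyte markers (camera adjusted p = 0.152), megakaryocyte markers (0.267), MHC class I genes (0.0503), MHC class II genes (0.888), stromal markers (0.462), the unfolded protein response (0.432) and G1 cyclins (0.939). Of the 21 macrophage and monocyte markers 8 fell and 2 rose (8 and 4 adjusted over the list alone). C1qa, C1qb and C1qc, picked after their values were seen, lay above all control arrays on each tumour array. Their signal was weak, as for C1qa (5.90 to 7.26 in tumours, controls at most 5.25). The MHC class I result depended on the processing, with 11 of 18 alternatives not passing (range 0.0262 to 0.529). For MHC class II and G1 cyclins the median and mean were above 0 (0.05 and 0.10, 0.19 and 0.07) while camera's direction was lower. For the unfolded protein response the median was -0.05 and the mean 0.06.

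In all, 5659 of 18193 genes differed between tumours and wild type cells, 3188 higher and 2471 lower in tumours, and 2671 of them by at least 2-fold. Camera called 25 of the 33 lists, 6 higher and 19 lower, and 2 of these held with an estimated correlation (NF-kB targets and B lineage transcription factors). The tumour cells and the sorted bone marrow cells differ in source, and the gate and handling of the tumour cells are not given.

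**Figure D1:**
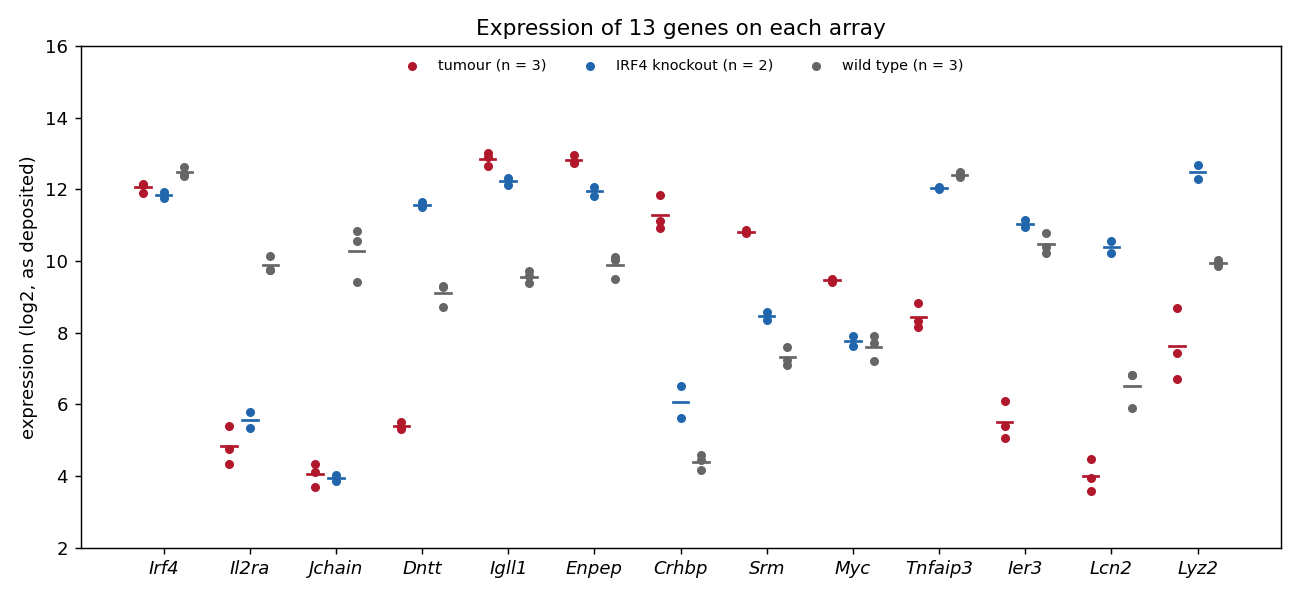
Log2 expression of 13 named genes on each array. Each point is 1 array, coloured by group, and each bar marks the mean of its group. Crhbp, Srm and Myc lie higher on the 3 tumour arrays than on the control arrays, Tnfaip3 and Ier3 lie lower, and Jchain is high on the wild type arrays alone among these 8.

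Against IRF4 knockout cells, the largest rise in tumours was that of Umod (45.1-fold, 11.16 ± 0.59 against 5.66 ± 0.34, log2 difference 5.49, SE 0.32, adjusted p = 3.08e-05). Crhbp was 37.6-fold higher and Ltbp2, a latent TGF-beta binding protein gene, was 8.11 ± 0.21 against a weak 3.18 ± 0.16 (log2 difference 4.94, SE 0.21). Popdc3, Napepld, Gpm6b and Prss23 were 13.6- to 16.5-fold higher. Radil was 13.9-fold higher (adjusted p = 0.00679), a call that ended without IRF4 knockout array 2 (3.61, adjusted p = 0.0593, range 2.61e-05 to 0.101 over the alternatives). The largest falls were in the chemokine receptor gene Ccr9 (114-fold, 3.33 ± 0.27 against 10.17 ± 0.17, SE 0.24, adjusted p = 4.77e-06) and the granule protein genes Ngp (98.2-fold), Lcn2 (84.3-fold), Camp (72.7-fold) and Ltf (50.5-fold). Other large falls were in Dntt (72.3-fold), the cytokine gene Il6 (51.1-fold) and Xist (89.2-fold).

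Ribosome biogenesis and Myc targets were higher in the tumours at 26 of 30 members and lower at 0 (28 and 0 adjusted over the list alone, median 1.16, camera adjusted p = 4.14e-15, and adjusted p = 0.0443 with an estimated correlation). Srm rose by 2.35 on the log2 scale (SE 0.16), Polr1b 3.88-fold and Wdr12 3.70-fold. Oxidative phosphorylation genes rose at 16 of 24 with 0 lower (18 and 0 adjusted over the list alone, median 0.45, camera adjusted p = 6.43e-07, and adjusted p = 0.214 with an estimated correlation). DNA replication (7 of 29 higher, 7 adjusted over the list alone), cholesterol synthesis (6 of 17, 10 adjusted over the list alone), glycolysis (8 of 16, 8 adjusted over the list alone) and mitosis (4 of 29, 0 adjusted over the list alone) were called higher too, at an adjusted p of 0.434, 0.223, 0.232 and 0.577 with an estimated correlation. Of the glycolysis and cholesterol lists 2 and 1 members fell. The glycolysis call was lost when arrays were centred on their medians (adjusted p = 0.0889) and without IRF4 knockout array 1 (0.111), within a range of 0.00265 to 0.232 and with 3 of 18 alternatives not passing. The mitosis call was lost in 7 of 18 alternatives, among them fry (0.173) and leaving out tumour 3 (0.142) or IRF4 knockout array 2 (0.144), within 0.00782 to 0.577. Myeloid markers were lower on the same tumour arrays, as was the Gapdh difference (1.56 to 1.67 against 2.23 to 2.37) but not that of beta-actin.

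NF-kB targets fell at 16 of 17 members with 0 higher (16 and 0 adjusted over the list alone, median -2.28, camera adjusted p = 1.43e-17, and adjusted p = 0.0147 with an estimated correlation). Ccl3 fell 46.4-fold, Tnfaip3 12.1-fold and Rel, an NF-kB subunit gene, 9.81-fold. Immediate early genes fell at 17 of 20 with 0 higher (19 and 0 adjusted over the list alone, median -2.47, camera adjusted p = 1.08e-17, and adjusted p = 0.0502 with an estimated correlation). Ier3 fell 46.2-fold and Atf3 36.3-fold. Interferon-stimulated genes fell at 20 of 22 with 0 higher (20 and 0 adjusted over the list alone, median -1.57, camera adjusted p = 8.17e-17, and adjusted p = 0.045 with an estimated correlation). Irf7 fell 8.17-fold and Oasl2 7.62-fold. B lineage transcription factors fell at 11 of 28 and rose at 1 (15 and 1 adjusted over the list alone, median -0.61, camera adjusted p = 1.46e-06, and adjusted p = 0.0386 with an estimated correlation), again with Id2 in the lead (14.5-fold). Adhesion genes fell at 9 of 21 (10 adjusted over the list alone, camera adjusted p = 8.99e-06, and adjusted p = 0.0462 with an estimated correlation), led by Ccr9. Early B stage genes fell at 7 of 19 and rose at 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0162, and adjusted p = 0.224 with an estimated correlation). Dntt fell most, and the call on the list ended without IRF4 knockout array 2 (adjusted p = 0.095, range 0.00123 to 0.224, with 3 of 18 not passing). Markers of several other cell types fell alongside these lists. The Gapdh difference was also lower (1.56 to 1.67 against 2.23 to 2.37), while that of beta-actin overlapped.

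Neutrophil markers were lower in the tumours at 13 of 16 members (13 adjusted over the list alone, median -3.98, camera adjusted p = 3.14e-14, and adjusted p = 0.0502 with an estimated correlation). Macrophage and monocyte markers fell at 13 of 21 and rose at 1 (13 and 3 adjusted over the list alone, median -1.47, camera adjusted p = 7.23e-07, and adjusted p = 0.115 with an estimated correlation). Lyz2 fell 29.3-fold and Fcgr3 12.5-fold. Progenitor markers fell at 12 of 14 (12 adjusted over the list alone, median -1.60, camera adjusted p = 7.73e-11, and adjusted p = 0.0502 with an estimated correlation). Hoxa9 fell 14-fold and Kit 8.20-fold. Dendritic cell markers fell at 9 of 12 (10 adjusted over the list alone, median -1.39, camera adjusted p = 6.4e-10, and adjusted p = 0.0443 with an estimated correlation). Also called lower were T cell (6 of 16), NK cell (5 of 12), erythroid (6 of 14) and megakaryocyte markers (4 of 10), late pre-B genes (6 of 18), B cell receptor signalling (9 of 27), leukaemia and lymphoma genes (10 of 30), p53 targets (9 of 20) and apoptosis regulators (5 of 19). In the same order 0, 0, 1, 0, 1, 2, 2, 3 and 1 members rose, and adjusted over the list alone the counts of lower members were 9, 7, 6, 5, 8, 10, 14, 9 and 5. With an estimated correlation their adjusted p was 0.104, 0.132, 0.289, 0.0502, 0.0519, 0.104, 0.104, 0.0906 and 0.211. Mature B cell genes (4 of 17 lower), MHC class I (4 of 11) and class II genes (1 of 10), the unfolded protein response (6 of 20) and cytokine receptors (9 of 21) were called lower too. In the same order 2, 1, 0, 2 and 2 members rose, and adjusted over the list alone 4, 5, 1, 7 and 9 were lower. These calls had an adjusted p of 0.132, 0.307, 0.381, 0.275 and 0.153 with an estimated correlation. These ended without 1 array for mature B cell genes (tumour 2, 0.0724, or IRF4 knockout 2, 0.106), MHC class II (tumour 3, 0.0698), the unfolded protein response (tumour 3, 0.101, or IRF4 knockout 2, 0.183) and cytokine receptors (IRF4 knockout 2, 0.0539). Over the alternatives these 4 ran from 0.00265 to 0.132, 2.26e-05 to 0.381, 0.00838 to 0.275 and 0.00184 to 0.153, with 4, 3, 6 and 2 of 18 not passing. Under fry the calls on DNA replication (0.0567, range 0.000166 to 0.434), MHC class I (0.0739, range 0.00106 to 0.307) and MHC class II (0.183) were lost. Plasma cell markers (camera adjusted p = 0.697), stromal markers (0.103) and G1 cyclins (0.194) were not called, and for these the median was 0.07, 0.03 and 0.15 while the mean and camera's direction were lower.

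The comparison called 3783 genes, 2028 higher and 1755 lower in tumours, and 1839 by at least 2-fold. Camera called 30 of the 33 lists, 6 higher and 24 lower, and 6 held with an estimated correlation. Centring each array on its median, which moved the median difference of all genes from 0.077 to 0.23, gave 4175 higher and 1491 lower. The balance turned to 775 higher and 1064 lower at a minimum of 2-fold, and to 1017 higher and 1279 lower (2296 in all) without IRF4 knockout array 2, so it depends on these choices.

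**Figure D2:**
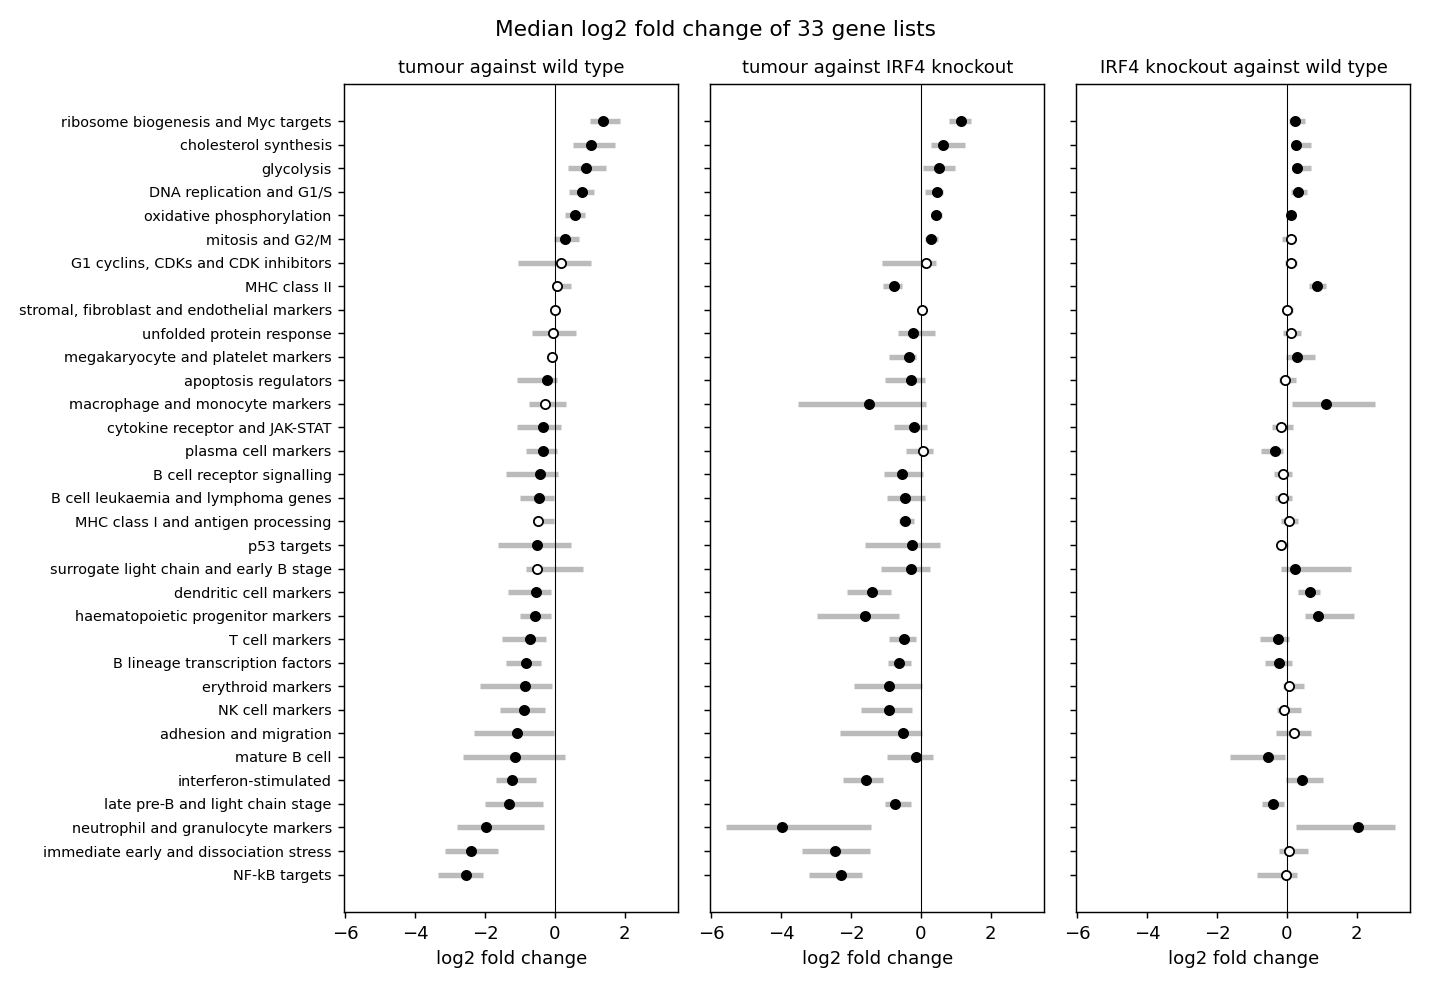
Log2 differences of the members of 33 gene lists in the 3 comparisons. Points mark the list's median and grey bars the 25th to 75th percentile of its members, and filled points mark lists with a camera adjusted p under 0.05. Ribosome biogenesis lies to the right in both tumour comparisons (1.37 and 1.16), NF-kB targets to the left (-2.55 and -2.28), and neutrophil markers lie to the right in IRF4 knockout against wild type (2.03).

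The series asked for genes specific to the tumours, and 3157 genes changed the same way against both control groups, 1811 higher and 1346 lower in tumours, with 15 genes called in opposite directions. Among them were the rises of Crhbp, Umod, Prss23, Ltbp2, Srm and Wdr12 and the falls of Ccr9, Ly6d, Tnfaip3, Nfkbie, Ier3, Id2 and Plk2. A change of at least 2-fold in both held for 1408 genes, 692 higher and 716 lower. Independent lists of these sizes would share 355 higher and 238 lower genes, a figure that leaves out the sharing of the tumour arrays. In 100 simulations of unchanged groups that shared the tumour arrays, 0 genes were called in both. With no change set, the adjusted p threshold makes such a result likely, so it gives no baseline for the 3157. Unadjusted signs were alike at 64.6% of simulated genes against 77.8% observed. The log2 differences of the 2 comparisons correlated across genes, which are not independent replicates, at r = 0.822 against 0.446 simulated, and their covariance was 0.545 against 0.0196, a difference of 0.525. The 3 tumours cannot be split into parts of at least 2 arrays, so part of the excess may come from the shared tumour arrays. Both control groups were also sorted bone marrow cells with far more Xist and a larger Gapdh difference than the tumours, though beta-actin overlapped. A change against both therefore does not by itself mark a gene as specific to the tumours. With arrays centred on their medians the split was 2731 higher and 1148 lower, and without IRF4 knockout array 2 it was 983 higher and 1065 lower (2048 in all).

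**Figure D3:**
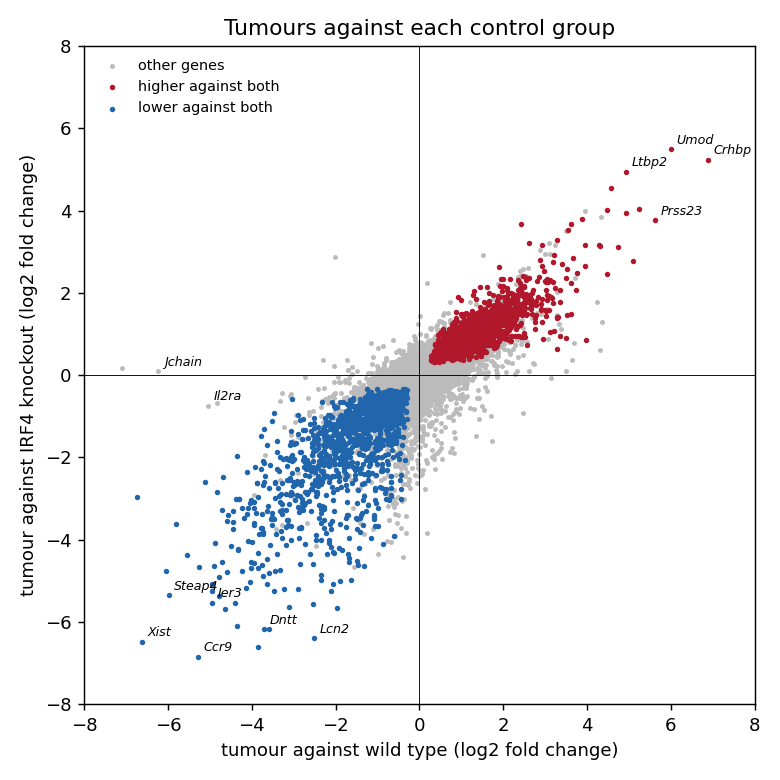
Log2 difference of each gene in tumours against wild type cells (horizontal) and against IRF4 knockout cells (vertical). Each point is 1 gene, with 1811 genes higher against both controls in red and 1346 lower against both in blue. The differences correlate across genes at r = 0.822, with the tumour arrays shared by both axes.

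Between the control groups, IRF4 knockout cells expressed more genes of early B cells and of myeloid cells, and fewer genes of late pre-B cells, than the wild type cells sorted on CD25. For the early B stage, neutrophil and late pre-B lists the adjusted p was 0.167, 0.167 and 0.158 with an estimated correlation, and no list held there. Olfm4 was 16.2-fold higher (7.62 ± 0.71 against 3.60 ± 0.15, SE 0.28, adjusted p = 0.000418). Lpl (lipoprotein lipase) was 16-fold, Lcn2 14.8-fold and Ltf 12.8-fold higher, the last 2 being neutrophil granule genes. Kcnf1, Sirpb1a and Gbp7 were 10.6- to 12.9-fold higher. Tm6sf1 was 10.4-fold higher (adjusted p = 0.0146), a call that ended without either IRF4 knockout array (adjusted p = 0.0503 and 0.118) or without any of the wild type arrays (0.0624, 0.0512 and 0.0521), within a range of 0.0002 to 0.118. Jchain was 80.7-fold lower in IRF4 knockout cells (3.94 ± 0.11 against 10.28 ± 0.75, SE 0.39, adjusted p = 0.000297). Erdr1 was 17.8-fold, Dmrt3 7.29-fold, Prg3 6.47-fold, Eaf2 6.10-fold and Polm, a polymerase of V(D)J joining, 5.84-fold lower. Cd2 was 6.52-fold lower (adjusted p = 0.00828), a call that ended without IRF4 knockout array 2 (adjusted p = 0.0793, range 0.0002 to 0.0793).

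Early B stage genes were higher in IRF4 knockout cells at 7 of 19 members with 0 lower (7 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.000355, and adjusted p = 0.167 with an estimated correlation). Igll1 was 6.32-fold, Dntt 5.55-fold and Kit, a growth factor receptor of progenitors, 4.99-fold higher. Progenitor markers rose at 9 of 14 (10 adjusted over the list alone, median 0.90, camera adjusted p = 2.35e-09, and adjusted p = 0.158 with an estimated correlation). Hoxa9 rose 5.30-fold and Cd34 3.97-fold. Late pre-B genes fell at 6 of 18 and rose at 1 (7 and 1 adjusted over the list alone, median -0.39, camera adjusted p = 0.00188, and adjusted p = 0.158 with an estimated correlation), which counts the gate gene Il2ra. Mature B cell genes fell at 3 of 17 (7 adjusted over the list alone, camera adjusted p = 0.00168, and adjusted p = 0.158 with an estimated correlation), with Fcmr 4.71-fold lower. Plasma cell markers fell at 3 of 12 (4 adjusted over the list alone, camera adjusted p = 0.00126, and adjusted p = 0.204 with an estimated correlation), Jchain and Irf4 among them. The kinase gene Pim2 was 4.26-fold and Syk 2.14-fold lower. B lineage transcription factors were called lower (6 of 28 lower and 2 higher, 9 and 2 adjusted over the list alone, camera adjusted p = 0.0298, and adjusted p = 0.167 with an estimated correlation). The call was lost in 6 of 18 alternatives, among them leaving out IRF4 knockout array 1 (adjusted p = 0.277) and centred arrays (0.15), within 0.00257 to 0.277. Of 21 immunoglobulin segment genes 5 fell and 0 rose. Neutrophil markers were higher on the same IRF4 knockout arrays. The Gapdh difference was lower there (2.23 to 2.37 against 2.59 to 3.02), while that of beta-actin overlapped.

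Neutrophil markers were higher in IRF4 knockout cells at 10 of 16 members with 0 lower (10 and 0 adjusted over the list alone, median 2.03, camera adjusted p = 6.81e-09, and adjusted p = 0.167 with an estimated correlation). Cd177 rose 9.98-fold. Mpo, a granule enzyme gene of immature granulocytes, was 8.26 ± 0.18 and 8.32 ± 0.47. Macrophage and monocyte markers rose at 11 of 21 (12 adjusted over the list alone, median 1.13, camera adjusted p = 2.84e-09, and adjusted p = 0.158 with an estimated correlation), with Adgre1 7.40-fold and Apoe 6.61-fold higher. Dendritic cell markers rose at 6 of 12 with 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.000271, and adjusted p = 0.158 with an estimated correlation). Megakaryocyte markers rose at 3 of 10 (4 adjusted over the list alone, camera adjusted p = 0.00626, and adjusted p = 0.158 with an estimated correlation), with Pf4 5.52-fold higher. The megakaryocyte call was lost in 2 of 17 alternatives (range 0.000357 to 0.158). T cell markers fell at 4 of 16 (7 adjusted over the list alone, median -0.25, camera adjusted p = 0.00472, and adjusted p = 0.252 with an estimated correlation), with Gata3 3.33-fold lower. This call ended without IRF4 knockout array 1 (adjusted p = 0.163, range 0.000112 to 0.252). Interferon-stimulated genes rose at 6 of 22 (11 adjusted over the list alone, camera adjusted p = 0.000355, and adjusted p = 0.252 with an estimated correlation), with Oasl2 3.06-fold higher. The interferon call ended without IRF4 knockout array 2 (adjusted p = 0.0865, range 7.91e-06 to 0.252). Ribosome biogenesis (4 of 30 higher), DNA replication (4 of 29), glycolysis (3 of 16), cholesterol synthesis (3 of 17, with 1 lower), MHC class II (1 of 10) and oxidative phosphorylation (1 of 24) were also called higher. Adjusted over the list alone these counts were 6, 9, 7, 5, 1 and 1. With an estimated correlation their adjusted p was 0.189, 0.41, 0.2, 0.41, 0.424 and 0.57. DNA replication, cholesterol synthesis and MHC class II lost their calls under fry (0.122, 0.0803 and 0.193), within 6.33e-06 to 0.41, 0.00179 to 0.41 and 5.22e-05 to 0.424. Oxidative phosphorylation lost its call in 7 of 18 alternatives, among them fry (0.193), centred arrays (0.084) and leaving out IRF4 knockout array 1 (0.0582) or wild type array 1 (0.209), within 0.00104 to 0.57. Fbl and Ldha, 2.70-fold and 2.75-fold higher, led the ribosome and glycolysis lists. The other 15 lists were not called, among them NF-kB targets (4 of 17 lower, camera adjusted p = 0.163) and immediate early genes (1 of 20 higher, 0.209). NF-kB targets passed under fry (adjusted p = 0.0475), while 15 of 18 alternatives did not pass (range 0.00811 to 0.781). For leukaemia and lymphoma genes the median was -0.10 and the mean 0.11, and for NK cell markers -0.07 and 0.19, while camera's direction was lower for both.

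IRF4 knockout and wild type cells differed at 1335 genes, 904 higher and 431 lower in the knockout, and at 635 by at least 2-fold. Centring arrays on their medians, which moved the median difference of all genes from -0.025 to -0.13, gave 686 higher and 905 lower, and repeated quantile normalization gave 881 and 758, so the balance of directions depends on the scaling. The count was 387 without IRF4 knockout array 2, and 591, 739 and 653 without wild type array 1, 2 and 3. Camera called 18 lists, 13 higher and 5 lower, and with an estimated correlation 0 (lowest adjusted p = 0.158). Genotype and sort gate differ together between these groups, so their effects cannot be separated here.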

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

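The tests of the Xist and Y-linked pattern, of the myeloid markers and of the immediate early and NF-kB genes were chosen only after these results were seen, and the 2 counts of other splits of the arrays were planned.

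Single Y-linked genes had signal on tumour arrays and not on control arrays, and the Kdm5d probe set quoted here did not stand for its gene in the comparisons. Uty and Eif2s3y were tested and not called (adjusted p = 0.29 and 0.231 for tumour against wild type). Kdm5d was 6.85 in tumour 1 and 7.29 in tumour 3 on the log2 scale, against at most 2.50 on the control arrays. Uty was 6.92 in tumour 1 (controls at most 3.06) and Eif2s3y 10.17 in tumour 3 (controls at most 2.80). In tumour 2 the values were 2.35, 3.03 and 3.18. The Kdm5d probe set that stood for the gene, with the highest mean, showed no such signal.

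Xist was 6.02 ± 0.29 in tumours (n = 3) and over 12 on each control array, so a sex difference between tumour donors and control mice is a candidate explanation. That tumours 1 and 3 came from males is consistent with at least 1 Y-linked gene each, the smaller excess over the controls being 4.35. That all 3 tumours came from males and expressed all 3 Y-linked genes is argued against, as the smallest of the 9 differences was -0.15 (Kdm5d in tumour 2). For tumour 2, a male cell that lost its Y chromosome and a female cell that lost Xist or an X chromosome both stay open, as does loss of single Y-linked genes in tumours 1 and 3. The sex of the mice is not given, and sex and tumour may therefore be mixed in both tumour comparisons.

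Myeloid markers were higher on the IRF4 knockout arrays than on the wild type arrays. A general loss of B lineage cells would raise all other cell types alike, but the neutrophil and T cell list medians (2.03 and -0.25, 16 genes each) lay 2.28 apart. A permutation of members reached 0.52 at its 95% limit (permutation p = 2e-05 from 100000 draws). It shuffles genes, which are not independent replicates, so this p does not measure the spread between arrays. The lists were chosen after their directions had been seen, and neither was called by camera with an estimated correlation (adjusted p = 0.167 and 0.252). Only the wild type gate adds CD25, and what that did to the T cell markers was not tested. The gap therefore cannot decide on a lower share of B lineage cells. Neutrophil lineage cells in the IRF4 knockout sort stay open, although a CD19 gate should remove them. Mpo did not follow (8.26 ± 0.18 against 8.32 ± 0.47), but as a gene of immature granulocytes it says nothing about more mature neutrophils. The 62.5% of the list called higher is the pattern itself and supports no source. Of the 16 genes 10 lay above the median gene level in wild type cells too, and 0 belong to another list. Myeloid genes expressed within CD19-positive cells, by genotype or by developmental stage, would give the same values and were not tested.

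Immediate early genes and NF-kB targets were lower in tumours than in both control groups. For the 37 genes as a set, a main source in myeloid cells that differed between the control groups like the neutrophil markers is argued against. The median difference of these genes was 0.05 between IRF4 knockout and wild type cells (95% bootstrap interval over genes, not arrays, -0.22 to 0.28). This lay below 1.01, a limit set at 0.5 of the neutrophil median. The medians were -0.05 and -0.03 for the members lower in tumours than in wild type or than in IRF4 knockout cells. Myeloid cells present alike in both control groups would give no such difference either, so this test cannot reach them and they stay open. Mpo, alike in both control groups and lower in tumours, had this profile. A myeloid share at single genes stays open, as 1 immediate early gene was called higher in IRF4 knockout than in wild type cells, with 4 NF-kB targets called lower. Handling of the sorted control cells may have induced these genes, and cannot be told apart from lower expression in the tumours (median -2.33 against IRF4 knockout cells), because the labels give no gate or handling for the tumours.

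For tumour against wild type, 1 of the 10 splits of the 6 arrays into groups of 3, the real one, gave as many genes (5659, and 0 at most in the others), and 10 splits are too few for a share under 0.05. For genes changed the same way against both controls, 1 of 100 assignments of the 8 arrays, the real one, gave as many (3157). The highest other, 3019, kept the 3 tumours as 1 group, as did 1 more with 2299, and the 97 that mixed tumours with controls gave at most 156. A random labelling of these arrays is thus argued against. The rank mainly restates that the tumour arrays lie apart from the controls, and it cannot tell what sets them apart.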

How the results depend on the processing

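All alternatives here were planned, and the ranges over single arrays leave out each of the 8 in turn. A minimum of 2-fold gave 2671 genes for tumour against wild type, 1839 for tumour against IRF4 knockout, 635 for IRF4 knockout against wild type and 1408 for both tumour comparisons. All probe sets, among which many share a gene, gave 11862, 6483, 2041 and 5476. A floor of 4 gave 735 for IRF4 knockout against wild type, and the cause was not tested. Leaving out single arrays gave 4528 to 5745, 2296 to 3679, 387 to 1604 and 2048 to 3096 genes, and 25 to 26, 25 to 30 and 16 to 21 called lists. With fewer arrays the tests have less power, and a lone IRF4 knockout array was assumed to vary like the other groups. Leaving out IRF4 knockout array 1 instead of 2 costs the same power, yet did not lower the count for IRF4 knockout against wild type. Many calls between the control groups therefore rest on array 2. Array 1 held 1112 to 1428 gene values identical to those of each tumour or wild type array, and array 2 held 287 to 339. The reason was not tested. Apart from the block below, all other settings kept these counts within 1.5 times. For tumour against wild type a filter on dim genes ended the calls on progenitor, erythroid, plasma cell, apoptosis and mitosis lists and left too few NK cell markers to test, and fry ended those on erythroid and mitosis lists. The filter left 24 called lists of 30 tested for tumour against IRF4 knockout and 15 for IRF4 knockout against wild type. Without it these were 30 and 18 of 33. An estimated correlation left 2, 6 and 0 called lists. With the mean of all probe sets of a gene, Irf4 in tumour against wild type turned to 0.04 (adjusted p = 0.865, range 0.00931 to 0.865) and Ighm in tumour against IRF4 knockout to 0.04 (adjusted p = 0.869, range 0.00824 to 0.869). For Irf4 the other probe set differed the other way, at 6.26, 6.77 and 7.06 in tumours against 6.22, 6.22 and 6.11 in wild type cells. For Ighm, dim probe sets that hardly differ or differ the other way enter the mean.

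The replicate number as a block gave 846 genes for IRF4 knockout against wild type, and 5176, 2877 and 2447 for the others, and the cause was not tested. The numbers gave no sign of pairing the samples, as the deviations of arrays with the same number correlated at -0.15 to 0.13. In 4 of 14 matches of an array to another group, the array with the same number correlated best. So few arrays cannot exclude a pairing.

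Of 395 named gene results under 17 alternatives, 6107 of 6657 values kept their direction and side of the threshold, 429 lost and 119 gained a call and 2 reversed. Sign changes between values that did not pass count as kept. Of the named genes called, 116 of 125, 90 of 117 and 32 of 79 were called in every alternative for tumour against wild type, tumour against IRF4 knockout and IRF4 knockout against wild type. Of 1773 list values 1625 kept their call, 120 lost and 28 gained it. Among called genes with other probe sets, a probe set was called the other way in 151 of 3436, 24 of 2178 and 2 of 787. Signal near the background, where GCRMA compresses differences, limits what can be seen for dim genes.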

Other observations

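The tests of neighbouring genes and the counts for single tumours were chosen only after the tumour arrays had been seen.

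The tumours differed from each other at single genes. With a distance of at least 3 on the log2 scale from both other tumours, 9 genes were higher and 7 lower in tumour 1, 7 and 30 in tumour 2, and 22 and 24 in tumour 3. Tumour 1 had little Ikzf3, a lymphoid transcription factor (4.92 against 10.60 and 10.68, controls 10.28 to 11.13), and little Satb1 (5.91, controls 9.80 to 10.32), and more Megf10 (9.59, controls at most 3.85) and Asns (9.66, controls at most 6.04). Gja1, a gap junction gene, was raised in tumours 1 and 3 (10.06 and 9.79) and not in tumour 2 (3.35, controls 3.37 to 5.97). Tumour 2 had less Rasgrp1 (4.15, controls 8.43 to 9.82) and more of the receptor kinase gene Ret (8.09, controls at most 6.98). Tumour 3 had less of the B cell kinase gene Blk (6.94, controls 9.98 to 11.45) and Lgals1 (7.36, controls 11.17 to 11.75). Il33 was raised in tumours 1 and 2 (8.87 and 9.10, controls at most 6.33) and not in tumour 3 (3.90), and Pkp4 was low in tumours 1 and 2 (3.26 and 3.28, controls at least 8.66). These are values of single arrays, chosen after they were seen.

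Igha and Jchain were high on the wild type arrays alone. Igha, the IgA constant region, was 12.22 to 13.22 on the wild type arrays and 5.26 to 5.85 on the other 5 arrays. Of the 21 immunoglobulin genes grouped by symbol, which include Igha, 5 were lower in IRF4 knockout than in wild type cells. At the 431 genes lower in IRF4 knockout than in wild type cells, the tumour mean lay nearer the IRF4 knockout mean in 388 (90%), below both controls in 298 and above both in 12. At the 904 genes higher in IRF4 knockout cells it lay nearer the knockout in 477 (52.8%), above both in 388 and below both in 324. The shares expected without a relation were not computed.

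A hypothesis for genes far lower in 1 tumour is loss of a chromosome stretch, which could take neighbouring genes together. Among 131 such genes (at least 2 lower on the log2 scale than in both other tumours), 4 pairs lay within 3 measured genes of each other, Septin10 with P4ha1, Mfhas1 with Lonrf1, Rnase4 with Ang and Samsn1 with Nrip1, against a median of 1 in 10000 random sets (permutation p = 0.038). Over 8 settings of size and distance 1 gave a p under 0.05, with a range of 0.035 to 0.35, and the settings were chosen after the genes had been seen. Some of these genes were low in the controls too, such as Septin10 (4.97 in tumour 2, controls 4.93 to 6.79). Of the 131 genes 59 had control values all above the median gene level and at least 2 above that tumour, and these formed 0 pairs (random median 0), which neither supports a loss nor excludes it.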
